A study of Sindora glabra with 12 samples.

How the data were processed

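Stem RNA of Sindora glabra was measured in 12 libraries, 3 untreated and 3 each after 10, 20 and 30 days of MeJA. Per the labels' protocols, total RNA was extracted with TRIzol and sequenced as read pairs on an Illumina instrument. The authors' matrix holds FPKM, fragments scaled by unigene length and library size, for 135521 unigenes with 1 column per library, per the file headers and the deposited values. The unigene names have the form that the assembler Trinity gives to genes, and the second deposited file holds 279115 predicted coding sequences with TransDecoder headers, from 81944 unigenes. The aligner, the quantifier, the versions and any filter are not given in the sources used here. The column totals differ between libraries (881717 to 1316787 FPKM), so the values were not rescaled to a common total before deposit. The values carry no counts, so the relative depth of each library was estimated from unigenes found in few libraries. It was read from the most frequent ratio of their values to those in untreated replicate 1. This assumes that the most frequent ratio comes from equal fragment counts, which was not tested. No interval from counting error can be given.

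Each predicted coding sequence was translated, and a unigene was placed in a protein family when the translation of any of its coding sequences held the family's motif. The motifs of 82 families in 29 lists, the tests, the alternatives and the naming rule were fixed before the data were examined. Every motif was also counted in shuffled proteins to show how often chance gives a match. A motif shows membership of a family and not the function of a single unigene, and near-identical copies within a family share reads in ways the files do not show. Of 37796 tested unigenes 30533 had a coding sequence.

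Values were taken as log2(FPKM + 1). Unigenes with at least 1 FPKM in at least 3 libraries were tested, 37796 in all. limma 3.58.1 under R 4.3.3 was fitted to all 12 libraries with 1 mean per group (8 residual degrees of freedom) and eBayes with a trend, and p-values were adjusted by the Benjamini-Hochberg method over all tested unigenes with a threshold of 0.05. Each MeJA time was compared with untreated stem, 20 with 10 days, 30 with 20 days, and all 4 groups by an F test. The 28 lists with at least 5 tested members were compared with the other tested unigenes by camera with a preset correlation of 0.01 and adjusted over the lists. No camera call held with a correlation estimated for each list. Changes are on the log2(FPKM + 1) scale, on which values near 0 are compressed. A unigene listed at 0 in a whole group is given by its values without a fold. The p-values measure the spread between these libraries, and the labels do not say whether they come from separate plants.

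By the naming rule, each list gives at most 2 called members with the largest rise and 2 with the largest fall, among those with at least 5 FPKM in the higher group. Where it has none, its member with the highest mean FPKM is named. No list had a member called over all unigenes, so each list is represented by its most abundant member. Over all unigenes the 2 largest rises and 2 largest falls that meet the same minimum are named by identifier. Unigenes outside this rule are marked as chosen after their values were seen.

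The alternatives were a pseudocount of 0.1 FPKM, no filter and a filter of 5 FPKM, equal FPKM totals, centring on the median log2 ratio, quantile normalization, the replicate number as a block, eBayes without the trend, array quality weights, a fit on the groups compared alone, list membership from complete coding sequences, camera with an estimated correlation, fry, and leaving out each library in turn. Chosen after seeing the data were the lists without families open to chance matches, the filter counted without untreated replicate 3, the lignin list mean as a covariate, and the average of the 3 MeJA times against untreated stem. Where comparisons share the untreated libraries, chance values came from 100 simulated sets of unchanged groups. Splits of the libraries into other groups were counted for each test over many unigenes.

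The fits were tested, for the comparison at 20 days, on simulated values with the means and residual spread of the 37796 unigenes over all 12 libraries. The changed unigenes were drawn from the more abundant ones only. Of 50 unigenes of each size in 10 runs, 5.8% of 2-fold, 50.4% of 4-fold, 74.6% of 8-fold and 83% of 16-fold changes were called, with 8.4 false calls per run. A list shifted by 1 on the log2 scale was called in 10 of 10 runs. The simulated libraries hold no differences shared between unigenes, such as those along the first component. Correlations, permutation tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.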

Results

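RNA was measured in the stem of Sindora glabra, a leguminous tree known for an oleoresin rich in terpenes, after treatment with methyl jasmonate (MeJA), a plant hormone that elicits defence responses. The 12 libraries fell into 4 groups of 3: untreated stem, and stem treated with MeJA for 10, 20 or 30 days. The labels give no day for the untreated libraries, so treatment and elapsed time cannot be told apart. Expression was deposited as FPKM for 135521 unigenes of a transcriptome assembly. The files pair no unigene with a gene name, so unigenes are given by protein family, read from a motif in their predicted protein, and numbered within the family by mean FPKM. Read counts were not used here, so depth is known only in relative terms. The most frequent ratio of values, over unigenes found in few libraries, put the depth at 0.697 to 1.52 times that of untreated replicate 1. FPKM totals ran from 881717 to 1316787. Values below are mean FPKM ± SD with n = 3 libraries per group, and changes are differences of log2(FPKM + 1) from the untreated group with their standard error.

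Libraries differed widely in transcripts of wood formation, within groups as well as between them. CCoAOMT 1, a lignin synthesis methyltransferase and the most abundant member of the phenylpropanoid and lignin list, ran from 14.56 FPKM in untreated replicate 3 to 3483.61 in MeJA 10 days replicate 3. Its group means were 751 ± 1090 FPKM in untreated stem and 1350 ± 1850, 1230 ± 1060 and 287 ± 140 at 10, 20 and 30 days. The mean log2 level of the 44 lignin list unigenes ran from 2.75 to 5.07 and followed that of the cellulose synthases, which make cell wall cellulose, over the 12 libraries (Pearson r = 0.968, permutation p = 1e-05, adjusted p = 2e-05 over 4 relations). This p is the smallest that 100000 permutations can give. Spearman rho was 0.902 (permutation p = 0.00014, adjusted p = 0.00028). Without untreated replicate 3 and MeJA 20 days replicate 2, the libraries farthest out, r was 0.945, and it was 0.983 for deviations from the group means. The first principal component held 31.45% of the variance, and 10.25% of its variance lay between groups, where chance gives 27.27%. Components 2, 3 and 4 held 13.81%, 10.79% and 9.461%, with 52.44%, 21.96% and 40% of their variance between groups, and none of these shares was tested. The lignin list itself did not pass the test against untreated stem (camera adjusted p = 0.0963, 0.362 and 0.958 at 10, 20 and 30 days). Of its members, laccase 18 had 0.777 ± 0.28 FPKM in untreated stem and 9.27 ± 5.6, 3.69 ± 1.28 and 8.19 ± 3.39 after MeJA, and CAD 8 had 12 ± 14.6 against 0.22 ± 0.0985, 0.167 ± 0.0764 and 0.127 ± 0.0723. Over the list alone laccase 18 passed as higher at 10 and 30 days (limma adjusted p = 0.00896 and 0.011) and CAD 8 as lower at all 3 times (0.0149, 0.0251 and 0.011). Both were chosen after their values were seen, and neither passed over all unigenes. The laccase and CAD motifs also matched shuffled proteins, in 8 unigenes against 31 and in 2 against 13.

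**Figure D1:**
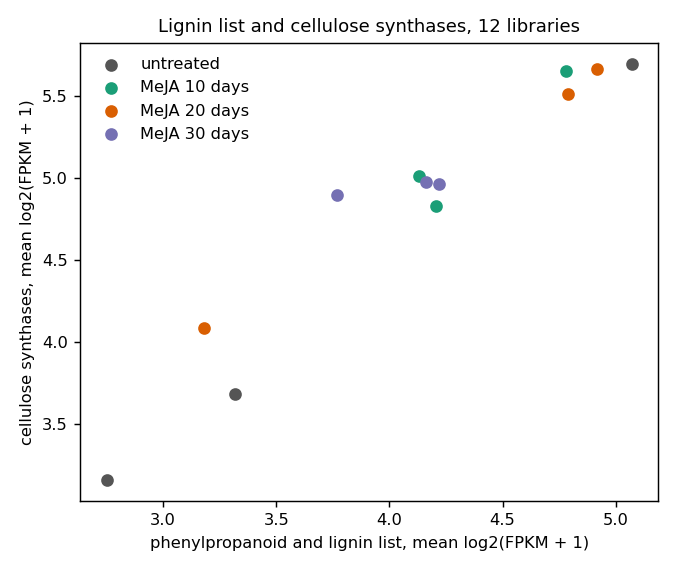
Mean log2(FPKM + 1) of the phenylpropanoid and lignin list (x axis) against that of the cellulose synthases (y axis), 1 point per library, coloured by group. The 12 libraries run along a single line (r = 0.968), with untreated libraries at both ends.

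Untreated replicate 3 also stood apart. It held 18883 unigenes at 1 FPKM or more that no other library reached, against 1790 to 4001 in the other 11 libraries, and these took 8.4% of its FPKM. Light-harvesting proteins, which bind chlorophyll in green tissue and algae, made up 15 of these unigenes (0.0794%), where no other library had more than 1 (0.0291% of its own). The 2 unigenes with the highest mean FPKM, which the files leave unnamed, took between 0.168% and 27.5% of a library's FPKM.

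**Figure D2:**
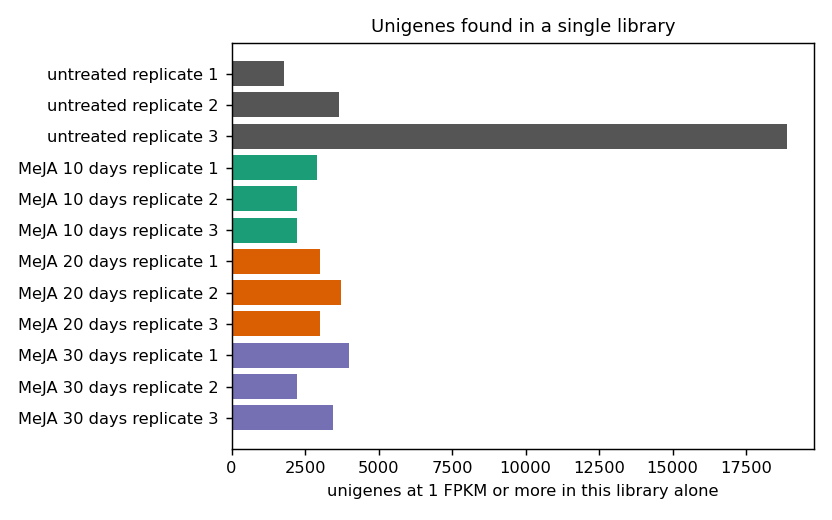
Number of unigenes at 1 FPKM or more in a single library (x axis, from 0), 1 bar per library, coloured by group. Untreated replicate 3 has 18883 such unigenes and the other 11 libraries have 1790 to 4001.

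Few single unigenes passed the test after MeJA, and all that did were found in some groups and listed at 0 in others. The files do not say whether a 0 is a true count of 0 or a value that a filter removed, and every call rests on such values. DN98062_c0_g1, which encodes a predicted protein of 69 amino acids, had 4.88, 8.07 and 13.96 FPKM in the untreated libraries and was listed at 0 in all 9 treated ones (limma adjusted p = 0.0211, 0.0211 and 0.0141 at 10, 20 and 30 days). DN61310_c5_g1, with no predicted protein, had 7.09, 5.16 and 3.82 FPKM at 10 days and was listed at 0 elsewhere (adjusted p = 0.0211). DN64360_c1_g1, also without a predicted protein, was listed at 0 in the untreated and 10-day libraries. It had 32.5, 74.64 and 18.56 FPKM at 20 days (adjusted p = 0.00314) and 31.87, 30.05 and 27.69 at 30 days (adjusted p = 0.00521). DN65535_c0_g1, outside the naming rule and chosen after its values were seen, had 5.09, 4.78 and 3.45 FPKM at 30 days and was listed at 0 elsewhere (adjusted p = 0.0141). In all, 2 of 37796 unigenes passed at 10 days (1 up and 1 down), 2 at 20 days (1 up and 1 down) and 3 at 30 days (2 up and 1 down), and each change exceeded 1 on the log2 scale. At an unadjusted p below 0.05 there were 1886, 2055 and 2281 unigenes, where chance alone gives 1890. These few calls do not show that few unigenes changed. In simulated values, 5.8% of 2-fold and 50.4% of 4-fold changes in the more abundant unigenes were called. Without untreated replicate 3 the counts were 15, 13 and 12, without untreated replicate 2 they were 0, 1 and 0, and without MeJA 20 days replicate 2 there were 34 at 20 days. They were 0, 1 and 3 with a pseudocount of 0.1 FPKM and with no filter, 0, 1 and 1 with a filter of 5 FPKM, and 0, 0 and 2 in a fit on the groups compared. The filter asks for 5 FPKM in 3 libraries. It left DN98062_c0_g1, DN61310_c5_g1 and DN65535_c0_g1 untested, so the loss of their calls there was fixed in advance. With the replicate number as a block DN64360_c1_g1 alone kept its calls, and the counts were 0, 1 and 1. Over all 12 runs that left out 1 library they ran from 0 to 15, from 1 to 34 and from 0 to 12.

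The plastid MEP pathway, which supplies precursors of monoterpenes and diterpenes, was lower after MeJA at all 3 times. Of its 9 tested unigenes, 8 lay below the untreated mean at each time, and the median change was -1.42, -1.45 and -0.903 at 10, 20 and 30 days. HDS 1, a late enzyme of the pathway and its most abundant unigene, had 232 ± 284 FPKM in untreated stem and 22.8 ± 8.74, 21.7 ± 5.09 and 40.7 ± 38.8 after 10, 20 and 30 days. Chosen after their values were seen, HDR 1, the last enzyme, had 207 ± 258 FPKM against 17.7 ± 9.31, 18.2 ± 9.03 and 21.7 ± 6.02, and MDS 1 had 92.5 ± 66.4 against 29.2 ± 4.51, 28.6 ± 4.96 and 33.2 ± 5.26. DXR 1, an early enzyme, had 47.7 ± 35.2 against 9.61 ± 2.96, 8.72 ± 1.58 and 21.8 ± 11.3, while DXS 1, the entry enzyme, had 20.8 ± 1.14 against 14.8 ± 13.6, 13.9 ± 6.77 and 30 ± 17. The list was lower by camera with adjusted p = 7.18e-07, 8.93e-07 and 4.07e-05, and had adjusted p = 0.586, 0.316 and 0.585 with an estimated correlation between members. No member passed over all unigenes. Adjusted over the list alone, 5 members fell at 10 days, 6 at 20 days and 0 at 30 days by limma, with 4 at an unadjusted p below 0.05 at 30 days. Untreated replicate 2 had the highest values (HDS 1 at 556.37 FPKM against 107.12 and 31.76), and without it the difference in list mean went from -1.43 to -0.924 at 10 and 20 days and from -0.992 to -0.485 at 30 days, with adjusted p of at most 0.00189.

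**Figure D3:**
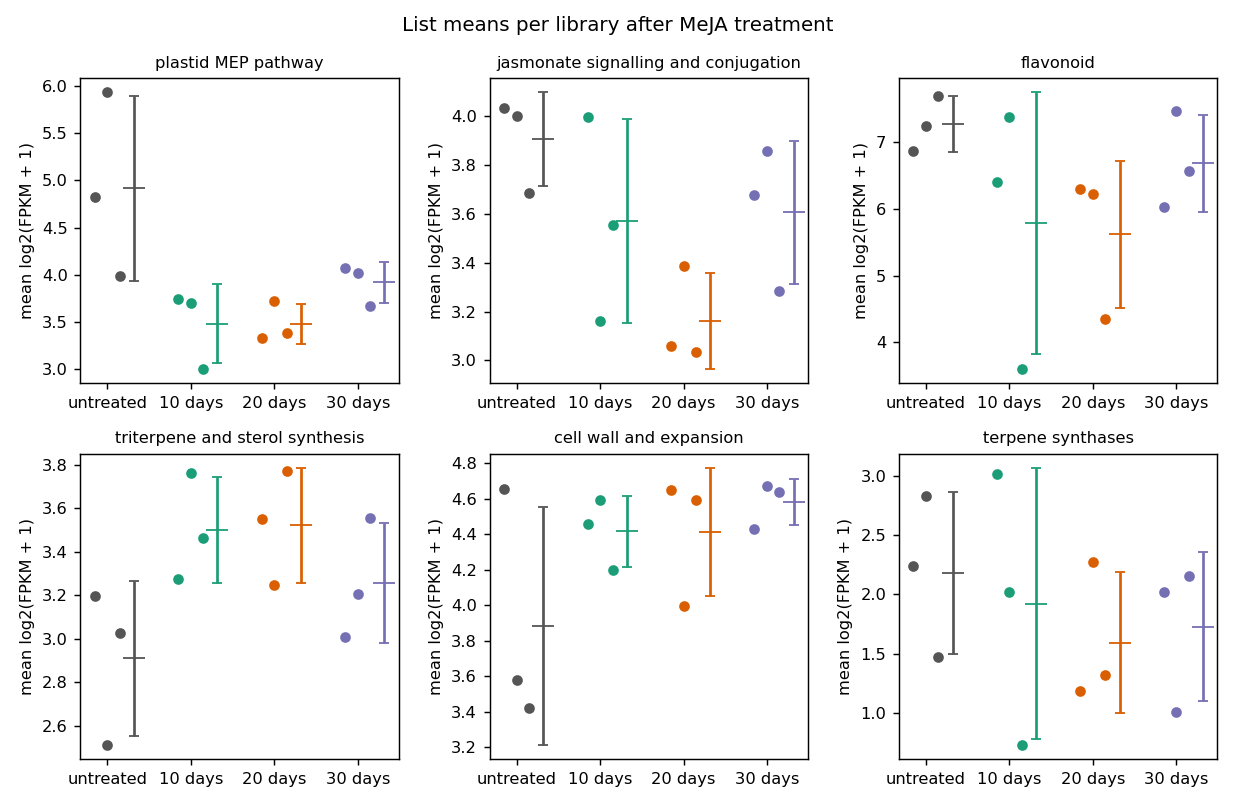
Mean log2(FPKM + 1) per library of 6 gene lists (y axis) in untreated stem and after 10, 20 and 30 days of MeJA (x axis), 3 points per group, with the group mean ± SD beside them. For the plastid MEP pathway the untreated libraries span 3.99 to 5.93 and the 9 treated ones 3 to 4.07, and for the flavonoid list MeJA 10 days replicate 3 lies lowest at 3.595.

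The mevalonate pathway, the prenyl diphosphate synthases and the terpene synthases did not pass as lists. Isopentenyl diphosphate isomerase 1, which interconverts the precursors of all terpenes, had 224 ± 122 FPKM in untreated stem and 70.1 ± 16.9, 73.2 ± 16.3 and 81.2 ± 19.4 at 10, 20 and 30 days. Its changes of -1.56, -1.49 and -1.34 (SE 0.378) passed when adjusted over the list alone (adjusted p = 0.0158, 0.0213 and 0.0413). They did not pass over all unigenes (0.697, 0.649 and 0.635). HMG-CoA synthase 3, of the same list and chosen after its values were seen, had 1.94 ± 2.22 FPKM against 11.5 ± 5.45, 9.79 ± 6.53 and 3.99 ± 2.15. Over the list alone it passed as higher at 10 days (adjusted p = 0.0219, and 0.943 over all unigenes). Their list, the cytosolic mevalonate pathway, did not pass (camera adjusted p = 0.948, 0.889 and 0.958). The terpene synthases, which make the terpenes themselves, varied between single libraries. Class I terpene synthase 1 had 103.4, 1353.73 and 0.57 FPKM in the 10-day libraries and at most 12.02 in any other library. Chosen after its values were seen, class I terpene synthase 2 had 51.72, 193.09 and 1.24 FPKM in untreated stem and at most 5.82 after MeJA. It had changes of -3.88 ± 1.37, -3.33 ± 1.37 and -4.02 ± 1.37 that did not pass (adjusted p = 0.996, 0.891 and 0.745). The list of 11 terpene synthases did not pass (camera adjusted p = 0.568, 0.739 and 0.286), nor did the 6 prenyl diphosphate synthases (0.168, 0.365 and 0.318). Prenyl diphosphate synthase 1, of the enzymes that build the terpene backbones, had 32 ± 19.7, 29.4 ± 5.96, 36.9 ± 20.6 and 33.4 ± 6.38 FPKM in untreated stem and at 10, 20 and 30 days. The motifs of class II diterpene cyclases and prenyl diphosphate synthases also matched shuffled proteins, in 6 unigenes against 7 and in 1 against 10.

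Triterpene and sterol synthesis was higher at 10 and 20 days, when 6 of its 7 tested unigenes lay above the untreated mean (median change 0.452 and 0.325). Squalene synthase 1, the entry enzyme, had 33 ± 3.98 FPKM in untreated stem and 37.8 ± 7.55, 39.8 ± 7.15 and 32 ± 4.79 after 10, 20 and 30 days. Oxidosqualene cyclase 1, which closes the triterpene rings and was chosen after its values were seen, had 10.5 ± 6.85 FPKM against 25 ± 3.18, 25.9 ± 7.65 and 14.6 ± 9.48. At 30 days 5 of the 7 unigenes lay above the untreated mean, with a median change of 0.439, and no test of a difference between times was made. The list passed camera at 10 and 20 days (adjusted p = 0.0307 and 0.0345) and not at 30 days (0.412), and had adjusted p = 0.66 and 0.407 with an estimated correlation. Without untreated replicate 2 the difference in list mean at 10 days went from 0.589 to 0.389. The call ended without untreated replicate 2 (adjusted p = 0.0915 and 0.114) or untreated replicate 3 (0.0505 and 0.0561). It also ended at 10 days without MeJA 10 days replicate 2 (0.279) or 3 (0.104), and at 20 days without MeJA 10 days replicate 2 (0.0543) or 3 (0.054) or MeJA 20 days replicate 1 (0.171) or 3 (0.108). At both times it ended with the lignin list mean as a covariate, chosen after seeing the data (0.179 and 0.166), a filter of 5 FPKM (0.183 and 0.182) or complete coding sequences (0.11 and 0.194). So it did with no filter (0.0917) or array quality weights (0.0525) at 10 days and in a fit on the groups compared at 20 days (0.0741).

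Transcripts of the jasmonate signalling and conjugation list were lower after MeJA, including those of JAZ repressors, which hold back jasmonate-responsive transcription. Lower transcripts of repressors do not show lower signalling, which was not measured. Of the 12 tested members of the signalling and conjugation list, 10, 12 and 9 lay below the untreated mean at 10, 20 and 30 days, with median changes of -0.293, -0.747 and -0.182. MYC2-type bHLH 1, of the transcription factors that JAZ proteins bind, had 64.8 ± 20.7 FPKM in untreated stem and 61.3 ± 26.1, 38.8 ± 16.5 and 59.2 ± 17.3 after 10, 20 and 30 days. Chosen after their values were seen, JAZ 2 had 72.4 ± 25.2 FPKM against 42.5 ± 12.2, 39.7 ± 8.27 and 36.6 ± 3.98. In the same order, JAZ 4 had 14.8 ± 3.36 against 6.56 ± 1.3, 4.52 ± 1.35 and 8.48 ± 3.01, and JAZ 6 had 7.58 ± 3.85 against 1.28 ± 1.22, 0.85 ± 0.784 and 1.34 ± 0.759. GH3 acyl amido synthetase 1, of a family that conjugates hormones with amino acids, had 2.32 ± 2.74 FPKM against 14.9 ± 16.1, 1.57 ± 1.74 and 19.2 ± 16.3, which did not pass (limma adjusted p = 1, 0.985 and 0.774). The list was lower by camera with adjusted p = 0.0112, 4.39e-06 and 0.00189, and had adjusted p = 0.66, 0.316 and 0.585 with an estimated correlation. Adjusted over the list alone, 1 member fell at 10 days (JAZ 6), 2 at 20 days (JAZ 4 and JAZ 6) and 3 at 30 days (JAZ 2, JAZ 3 and JAZ 6). At 10 days the call ended without untreated replicate 1 (adjusted p = 0.215) or MeJA 10 days replicate 2 (0.276) and with array quality weights (0.0743). The difference in list mean went from -0.336 to -0.131 at 10 days without MeJA 10 days replicate 2 (-0.549 without replicate 1), and from -0.301 to -0.141 at 30 days without MeJA 30 days replicate 3.

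Jasmonate synthesis did not pass as a list of 17 (camera adjusted p = 0.948, 0.889 and 0.958). 12-oxophytodienoate reductase type 1, of the enzyme family that reduces the jasmonate precursor, had 143 ± 109 FPKM in untreated stem and 310 ± 101, 252 ± 68.6 and 370 ± 144 at 10, 20 and 30 days. Its changes were 1.32 ± 0.533, 1.05 ± 0.533 and 1.54 ± 0.533 and did not pass (limma adjusted p = 0.996, 0.936 and 0.745).

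Flavonoid synthesis was lower at all 3 times, with all 9 unigenes below the untreated mean and median changes of -1.49, -1.6 and -0.498. Flavanone 3-hydroxylase 1 had 840 ± 316 FPKM in untreated stem and 429 ± 447, 251 ± 73 and 633 ± 350 after 10, 20 and 30 days. The same unigene is the most abundant of the 2-oxoglutarate dioxygenases, a list of 22 that did not pass (camera adjusted p = 0.948, 0.539 and 0.598). DFR type 1, a later enzyme chosen after its values were seen, had 402 ± 76.8 FPKM against 193 ± 171, 136 ± 84.2 and 260 ± 154. Chosen in the same way, chalcone or stilbene synthase 1 had 328 ± 88.9 against 175 ± 167, 103 ± 59.2 and 227 ± 149. The list passed camera with adjusted p = 8.95e-05, 1.79e-05 and 0.031. With an estimated correlation, which was 0.916 between its members, the adjusted p was 0.66, 0.698 and 0.817. Adjusted over the list alone no member fell by limma at any of the 3 times, and 1, 1 and 0 did at an unadjusted p below 0.05. At 10 days the call ended without MeJA 10 days replicate 3 (adjusted p = 0.108), when the difference in list mean went from -1.48 to -0.386 (-2.27 without replicate 2). At 20 days it went from -1.65 to -1.01 without MeJA 20 days replicate 3. At 30 days it went from -0.585 to -0.257 without MeJA 30 days replicate 1, -0.974 without replicate 2 and -0.372 without untreated replicate 3. The 30-day call ended without untreated replicate 1 (0.1), untreated replicate 3 (0.15) or MeJA 30 days replicate 1 (0.335), or when each library was centred on its median log2 ratio (0.12) or quantile normalized (0.277). It also ended with the lignin list mean as a covariate, chosen after seeing the data (0.0946), with no filter (0.233) and with array quality weights (0.103).

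Cell wall genes had higher group means after MeJA. At 10, 20 and 30 days 46, 48 and 53 of 62 tested unigenes lay above the untreated mean, with median changes of 0.422, 0.471 and 0.75. Expansin 1, of a family that loosens the wall during growth, had 403 ± 349 FPKM in untreated stem and 780 ± 258, 851 ± 319 and 1080 ± 177 after 10, 20 and 30 days. Chosen after their values were seen, expansin 2 had 84 ± 74.8 FPKM against 236 ± 84.4, 231 ± 89.3 and 272 ± 58.6, and XTH 1, a xyloglucan-modifying enzyme, had 94.8 ± 40.7 against 166 ± 21.4, 167 ± 30.4 and 161 ± 25.3. The list passed camera with adjusted p = 0.000482, 0.000676 and 0.00111, and had adjusted p = 0.66, 0.731 and 0.711 with an estimated correlation. Adjusted over the list alone no member rose or fell by limma. At an unadjusted p below 0.05, 8, 8 and 7 members rose and 1, 4 and 1 fell. The cell wall list, which holds the cellulose synthases, had a mean of 4.652 in untreated replicate 1 against 3.578 and 3.42 in replicates 2 and 3. Its treated libraries ran from 4 to 4.67, with 1 of 9 above all untreated ones. The lignin list mean was 5.073 in untreated replicate 1 against 3.318 and 2.75 in replicates 2 and 3. With it as a covariate, an alternative chosen after seeing the data, the call ended at 10 and 20 days (adjusted p = 0.255 and 0.146). The call ended without untreated replicate 3 at all 3 times (adjusted p = 0.115, 0.161 and 0.15) and without untreated replicate 2 at 20 and 30 days (0.0633 and 0.0806). It also ended without MeJA 10 days replicate 2 at 10 days (0.108) and without MeJA 20 days replicate 1 at 20 days (0.18). The differences in list mean of 0.534, 0.529 and 0.696 went to 0.918, 0.914 and 1.08 without untreated replicate 1, and at 10 and 20 days to 0.302 and 0.298 without untreated replicate 3.

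Among stress and defence genes, 2 lists passed, each at a single time. Heat shock and dehydration genes were higher at 10 days, with 27 of 39 unigenes above the untreated mean and a median change of 0.542 (camera adjusted p = 0.00282, and 0.603 and 0.318 at 20 and 30 days). At 20 and 30 days 26 of the 39 lay above the untreated mean, the mean change was 0.571, 0.176 and 0.591 at the 3 times, and no test of a difference between times was made. At 10 days the adjusted p was 0.66 with an estimated correlation, and the call ended without MeJA 10 days replicate 2 (0.0917) or 3 (0.261) and with array quality weights (0.0541). Dehydrin 1, a protein of water stress and the most abundant member, had 1780 ± 542 FPKM in untreated stem and 1410 ± 567, 1190 ± 187 and 1330 ± 539 at 10, 20 and 30 days. HSP20 3, a small heat shock protein chosen after its values were seen, had 88.7 ± 54.4 FPKM against 432 ± 219, 142 ± 61 and 617 ± 616. NBS resistance genes, intracellular immune receptors, were higher at 30 days, with 134 of 174 unigenes above the untreated mean and a median change of 0.36, where the median over all tested unigenes was 0.132 (camera adjusted p = 0.00528, against 0.168 and 0.792 at 10 and 20 days). The adjusted p was 0.835 with an estimated correlation, and 0.562 with the preset one without untreated replicate 1, when the difference in list mean went from 0.425 to 0.2. The call also ended with array quality weights (0.24) and complete coding sequences (0.348). NBS domain 1 had 82.1 ± 62.2 FPKM in untreated stem and 123 ± 37, 110 ± 59.4 and 189 ± 28.3. The defence protein list of 49, which holds chitinases and other pathogenesis-related proteins, did not pass (camera adjusted p = 0.791, 0.603 and 0.564). Its most abundant member, PR1 1, had 157 ± 221 FPKM against 383 ± 103, 231 ± 135 and 331 ± 234. Chosen after their values were seen, Bet v 1 (PR10) 1 had 28 ± 18 FPKM against 1.45 ± 1.36, 5.49 ± 3.26 and 0.617 ± 0.559, and thaumatin 3 had 248 ± 235 against 7.16 ± 3.74, 21.4 ± 33.2 and 13 ± 9. Over the list alone PR10 1 passed as lower at 10 and 30 days (limma adjusted p = 0.00923 and 0.00279) and thaumatin 3 at 10 days (0.0345), and neither passed over all unigenes. The PR10 motif matched 1 unigene and also 1 in shuffled proteins, so the name PR10 1 is open to chance. Other motifs of this list matched shuffled proteins too: legume lectins in 40 unigenes against 29, Kunitz inhibitors in 7 against 5 and GH18 chitinases in 5 against 16. Class III peroxidases did not pass either (adjusted p = 0.619, 0.365 and 0.412), with class III peroxidase 1 at 48.1 ± 43.2 FPKM against 43.3 ± 34, 54.5 ± 39.6 and 74.5 ± 14. Class III peroxidase 2, chosen after its values were seen, had 25.7 ± 12.3 against 55.9 ± 36.6, 46.4 ± 8.2 and 85.4 ± 10.2, and passed as higher over the list alone at 30 days (limma adjusted p = 0.0328, and 0.554 over all unigenes).

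Among transcription factors and transporters, the R2R3-MYB and ABCG lists each passed at a single time. ABCG transporters, which export resins and other lipids, passed as lower at 20 days (camera adjusted p = 0.0498, median change -0.0471, 12 of 21 members lower, and 0.197 and 0.0697 at 10 and 30 days). The adjusted p was 0.407 with an estimated correlation. The call ended without untreated replicate 1 (0.187) or 3 (0.106), MeJA 10 days replicate 1 (0.0508), 2 (0.0589) or 3 (0.0705), or MeJA 20 days replicate 1 (0.116) or 3 (0.108), and after centring each library (0.0615). Without MeJA 20 days replicate 1 the difference in list mean went from -0.46 to -0.285. The call also ended with complete coding sequences (0.692), no filter (0.219), a filter of 5 FPKM (0.142), array quality weights (0.18), eBayes without the trend (0.0549) and the lignin list mean as a covariate, chosen after seeing the data (0.146). With the replicate number as a block it ended too. ABCG transporter 1 had 54.4 ± 14 FPKM in untreated stem and 39.6 ± 14.9, 32.5 ± 4.41 and 56.5 ± 41.6 at 10, 20 and 30 days. R2R3-MYB factors passed as lower than the other tested unigenes at 30 days (camera adjusted p = 0.0325, and 0.568 and 0.253 at 10 and 20 days). Against untreated stem 40 of 79 members were higher, the median change was 0.00376 and the mean -0.0878. The median over all tested unigenes was 0.132. The difference in list mean turned to 0.0528 without untreated replicate 1 and reached -0.232 without untreated replicate 3. The adjusted p was 0.585 with an estimated correlation, and the call ended without untreated replicate 1 (0.562), MeJA 30 days replicate 2 (0.0657) or 3 (0.0832), after centring (0.152) and after quantile normalization (0.0545). It also ended with a pseudocount of 0.1 FPKM (0.098), no filter (0.436), array quality weights (0.14), complete coding sequences (0.275) and, chosen after seeing the data, the filter counted without untreated replicate 3 (0.0639). R2R3-MYB 1 had 177 ± 83 FPKM in untreated stem and 88.4 ± 68.9, 40.9 ± 5.86 and 92.1 ± 38.9. R2R3-MYB 58, chosen after its values were seen, had 7.38, 15.01 and 5.58 FPKM in untreated stem and at most 0.88 in the 9 treated libraries. Its changes of -3.15 ± 0.398, -3.02 ± 0.398 and -2.94 ± 0.398 passed when adjusted over the list alone (adjusted p = 0.000633, 0.00092 and 0.00119) but not over all unigenes (limma adjusted p = 0.0757, 0.11 and 0.0633). R2R3-MYB 35, chosen in the same way, had 12.4 ± 2.31 FPKM against 2.32 ± 1.68, 2.76 ± 1.55 and 9.05 ± 2.17, and passed as lower over the list alone at 10 and 20 days (adjusted p = 0.0122 and 0.0285, and 0.487 and 0.505 over all unigenes).

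The other regulators did not pass as lists at any time. Camera adjusted p at 10, 20 and 30 days was 0.948, 0.253 and 0.958 for WRKY factors and 0.568, 0.119 and 0.958 for AP2/ERF factors. It was 0.568, 0.739 and 0.958 for NAC factors, 0.568, 0.186 and 0.958 for bHLH factors, and 0.568, 0.894 and 0.958 for auxin and ethylene genes. WRKY 1 had 90.5 ± 68.5 FPKM in untreated stem and 79.2 ± 46.4, 70.7 ± 31 and 129 ± 34.2 at 10, 20 and 30 days. AP2/ERF 1 had 246 ± 18.7, 292 ± 43.7, 258 ± 81.1 and 271 ± 38.8 FPKM in the same order. NAC 1 had 65.5 ± 14.6, 61.6 ± 13.8, 61.2 ± 36.6 and 67.2 ± 17.2. For bHLH 1 the values were 233 ± 115, 183 ± 77, 173 ± 89.3 and 207 ± 20.7, and for Aux/IAA 1 they were 223 ± 58.2, 222 ± 30.7, 206 ± 39.9 and 253 ± 16.1. The bHLH and Aux/IAA motifs also matched shuffled proteins, in 6 unigenes against 60 and in 5 against 24.

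Lists for modifying enzymes and for the make-up of the samples gave 1 call. Housekeeping genes passed as lower than the other tested unigenes at 30 days (camera adjusted p = 0.031, and 0.568 and 0.45 at 10 and 20 days). Against untreated stem their median change was -0.0704, the mean was 0.0185 and 51 of 90 members were lower. The median over all tested unigenes was 0.132, so the call does not show a list lower than in untreated stem. The difference in list mean of 0.0187 ran from -0.144 without untreated replicate 3 to 0.182 without untreated replicate 1. With an estimated correlation the adjusted p was 0.586, and the call ended without untreated replicate 1 (0.699) or MeJA 30 days replicate 1 (0.309) and after quantile normalization (0.492). It also ended without families open to chance matches, chosen after seeing the data (0.853), with complete coding sequences (0.313), no filter (0.204), a filter of 5 FPKM (0.342) and array quality weights (0.35). Ubiquitin 1 had 3230 ± 1350 FPKM in untreated stem and 3120 ± 1090, 2410 ± 387 and 2430 ± 777 at 10, 20 and 30 days, and its motif matched shuffled proteins in 8 unigenes against 67. Cytochromes P450, which oxidise terpenes among many other substrates, did not pass (adjusted p = 0.948, 0.889 and 0.318), with cytochrome P450 1 at 416 ± 334, 496 ± 370, 509 ± 381 and 249 ± 29.7 FPKM. UDP-glycosyltransferases did not pass (0.568, 0.539 and 0.958), with UDP-glycosyltransferase 1 at 136 ± 61.9, 218 ± 57.8, 117 ± 9.3 and 238 ± 80.7. Green tissue markers did not pass (0.181, 0.965 and 0.0697), with light-harvesting protein 1 at 80.1 ± 94.6, 69 ± 46.7, 81.2 ± 43.6 and 131 ± 44. Cell division genes did not pass (0.401, 0.197 and 0.1), with histone H2B 1 at 917 ± 71.7, 901 ± 512, 798 ± 143 and 1150 ± 446. The fungal marker list did not pass (0.948, 0.792 and 0.958), and its tested members all carry the chitin synthase motif, which is open to chance matches, with chitin synthase 1 at 38.4 ± 8.76, 38 ± 10.6, 30.1 ± 11.3 and 36.6 ± 3.6. The organelle-encoded list had too few tested members for the test, and COX1 1 was at 5.09 ± 1.95, 9.37 ± 8.52, 8.58 ± 2.96 and 5.72 ± 2.86 FPKM.

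Over all lists, 6 of 28 passed camera at 10 days (3 higher and 3 lower), 6 at 20 days (2 higher and 4 lower) and 7 at 30 days (2 higher and 5 lower). Higher and lower here are relative to the other tested unigenes. With an estimated correlation 0 passed at each time, with smallest adjusted p of 0.586, 0.316 and 0.585, and by fry, which tests whether a list moves one way, 0 passed with 0.438, 0.177 and 0.665. At an unadjusted p below 0.05 camera gave 8, 7 and 10 lists.

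Between MeJA times the same unigenes stood out. DN61310_c5_g1 was lower and DN64360_c1_g1 higher at 20 than at 10 days (limma adjusted p = 0.0155 and 0.00314, 2 of 37796 unigenes, 670 at an unadjusted p below 0.05). Of the 12 runs that left out 1 library, both calls held only without MeJA 10 days replicate 3. The fall was also lost with a pseudocount of 0.1 FPKM and with no filter, and neither passed in a fit on the groups compared. A filter of 5 FPKM left DN61310_c5_g1 untested. DN65535_c0_g1 was the 1 unigene that differed between 30 and 20 days (adjusted p = 0.0305, 1434 unadjusted), and this call ended when any 1 library was left out except MeJA 10 days replicate 2, without which 3 unigenes passed. It also ended with a pseudocount of 0.1 FPKM, no filter, equal totals, centring, a fit on the groups compared and, chosen after seeing the data, the lignin list mean as a covariate. A filter of 5 FPKM left DN65535_c0_g1 untested too. Over the 4 groups together 4 unigenes passed limma's F test (1398 unadjusted). Leaving out 1 library gave from 1, without untreated replicate 2 among others, to 12, without untreated replicate 3. The unadjusted counts of 670, 1434 and 1398 all lie below the 1890 that chance alone gives, and the reason was not tested.

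The 3 comparisons with untreated stem share their 3 control libraries. The covariance of their log2 changes was 0.313 for 10 and 20 days, 0.26 for 10 and 30 days and 0.252 for 20 and 30 days. Simulated unchanged groups, each set with a redrawn control group shared by its comparisons, gave 0.206 ± 0.16, 0.224 ± 0.171 and 0.209 ± 0.156 (mean ± SD of 100 simulations). Of these, 23, 30 and 31 simulations were at least as large. The correlations were 0.742, 0.665 and 0.597, against 0.44, 0.474 and 0.47 in the simulations. DN98062_c0_g1 was the fall shared by each pair and DN64360_c1_g1 the rise shared by 20 and 30 days. Independent lists of these sizes would share 2.6e-05 falls for each pair and 5.3e-05 rises for 20 and 30 days, but these figures leave out the shared controls. The 20 simulated fits shared none. They redrew residuals around the mean of each unigene, which cannot give a unigene at 0 in whole groups, so this count is no test of these calls. Part of any excess may come from the shared controls, which are too few to be split.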

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

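In this part the tests of a difference between times and the counts of splits were fixed before the data were examined. The average over the 3 times and the lignin list mean as a covariate were chosen after seeing the data. Levels differed between MeJA times for 3 unigenes, by limma's test of the difference itself, and elapsed time cannot be told apart from MeJA. DN61310_c5_g1 was lower at 20 than at 10 days (adjusted p = 0.0155) and DN64360_c1_g1 was higher (0.00314). DN65535_c0_g1, chosen after its values were seen, was higher at 30 than at 20 days (0.0305). The calls for 20 against 10 days both held in 1 of 12 runs without 1 library, and that of DN65535_c0_g1 in 1. The calls of DN61310_c5_g1 and DN65535_c0_g1 were lost with a pseudocount of 0.1 FPKM and with no filter. The filter of 5 FPKM in 3 libraries left both untested, so it says nothing about these calls. In a fit on the groups compared all 3 calls were lost. That of DN65535_c0_g1 was also lost with equal totals, centring and the lignin covariate, an alternative chosen after seeing the data. Each unigene was listed at 0 in all 3 libraries of 1 of the times compared, and none of the 3 has a predicted protein.

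With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For 20 against 10 days 6 of the 10 splits gave at least the real 2 unigenes (highest other 15), and for 30 against 20 days 4 gave at least the real 1 (highest other 4). Against untreated stem, 6 of 10 splits gave at least 2 unigenes at 10 days (highest other 4), 5 gave at least 2 at 20 days (highest other 1257) and 3 gave at least 3 at 30 days (highest other 6). The split with 1257 set untreated replicate 1 and MeJA 20 days replicates 1 and 3 against the rest, which points to a structure of the samples. These 3 libraries had the highest lignin list means of the 6 (5.073, 4.918 and 4.791 against 2.75 to 3.318). For lists, 7, 4 and 3 of the 10 splits gave at least the real 6, 6 and 7 at 10, 20 and 30 days (highest other 7, 10 and 7). Of 100 drawn splits of the 12 libraries, 63 gave at least the 4 unigenes of the F test (highest other 1701) and 25 at least the 5 of the average over the 3 times (highest other 5224), so chance cannot be excluded for either count. Splits that call so many more unigenes than the real groups point to a structure of the samples, and whether it is the same one was not tested.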

How the results depend on the processing

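Of the alternatives in this part, those chosen only after the data were seen are the lignin list mean as a covariate, the filter counted without untreated replicate 3, the lists without families open to chance matches, and the average over the 3 times. The lower plastid MEP list kept its call at all 3 times in all 12 runs without 1 library and in 14 of 14 other settings, apart from an estimated correlation and fry. The lower jasmonate signalling list at 20 and 30 days and the lower flavonoid list at 20 days did so too, although the size of some differences moved by over 1.5 times without 1 library. Over all called lists, 415 alternative values stayed past the threshold, 117 did not and 0 reversed in the direction given by the list test. For camera that direction is relative to the other tested unigenes. The difference in list mean from untreated stem did change sign for 2 lists called at 30 days. For R2R3-MYB factors it went from -0.088 to 0.0528 without untreated replicate 1. For housekeeping genes it went from 0.0187 to -0.144 without untreated replicate 3. Of the counts over all unigenes and lists, 123 alternative values stayed within 1.5 times the count given and 104 moved. Where a count moved, the cause was not tested, except that fewer libraries or unigenes entered where a library was left out or the filter raised.

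Counts of unigenes follow in the order 10, 20 and 30 days against untreated stem. They were 0, 1 and 3 with a pseudocount of 0.1 FPKM and also with no filter, 0, 1 and 1 with a filter of 5 FPKM, 4, 4 and 6 after quantile normalization and 0, 0 and 2 in a fit on the groups compared. Centring gave 5 at 30 days. Without the trend there were 3, 3 and 10, and with array quality weights 2, 8 and 20. The filter counted without untreated replicate 3 gave 1, 1 and 2, and the lignin covariate 0, 2 and 3. DN98062_c0_g1 was not tested under that filter. The filter of 5 FPKM left DN98062_c0_g1, DN61310_c5_g1 and DN65535_c0_g1 untested, so these lower counts do not show that their calls failed. For 20 against 10 days there was 1 with a pseudocount of 0.1, with no filter and with a filter of 5 FPKM, and 0 in the fit on the groups compared. For 30 against 20 days there were 0 with no filter, a filter of 5 FPKM, equal totals, centring, the groups compared and the lignin covariate, and 11 with weights. The F test gave 2 with a pseudocount of 0.1, 1 with a filter of 5 FPKM, 7 after quantile normalization, 10 without the trend and 16 with weights. At 10 days a count of 0 stood beside 1034 (without untreated replicate 2) to 3727 (no filter) unigenes at an unadjusted p below 0.05 by limma. For 30 against 20 days it stood beside 796 (filter of 5 FPKM) to 3355 (no filter).

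Leaving out 1 library gave 0 to 15, 1 to 34 and 0 to 12 unigenes at 10, 20 and 30 days, 1 to 2 for 20 against 10 days, 0 to 3 for 30 against 20 days and 1 to 12 in the F test. The highest counts came without untreated replicate 3 (15, 13 and 12) and MeJA 20 days replicate 2 (34 at 20 days), and these included the 2, 2 and 3 unigenes called in all libraries. Lists ran from 3 to 8, 4 to 7 and 4 to 8. The average over the 3 times ran from 0 without untreated replicate 2 to 25 without MeJA 20 days replicate 2. At 30 days the median change of all unigenes was 0.132 as deposited, 0.199 with equal totals, -0.0185 after centring and -0.0333 after quantile normalization.

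Lists called at 10, 20 and 30 days numbered 0, 0 and 0 with an estimated correlation and by fry, 5, 3 and 7 with the lignin covariate and 5, 4 and 4 from complete coding sequences, with 4 at 30 days under weights. With the replicate number as a block there were 0, 1 and 1 unigenes against untreated stem, 1 for 20 against 10 days, 0 for 30 against 20 days, 1 in the F test and 1 for the average over the 3 times, and 6, 5 and 8 lists, without the ABCG list at 20 days (adjusted p = 0.06). Under the block DN64360_c1_g1 kept its calls at 20 and 30 days but not in the average over the 3 times, where the 1 call was a fall, and at single times DN98062_c0_g1, DN61310_c5_g1 and DN65535_c0_g1 did not pass. The sample titles share a stem per replicate number, and the labels do not say whether it marks the same tree. The values left pairing by number open. Deviations from the group means correlated at -0.405 to 0.514 between libraries of the same number, with a mean of 0.0462, against a mean of -0.0239 between other numbers. Of the same-number pairs 8 of 18 lay above 0.1, and 7 of 12 libraries correlated best with their own number, counts not tested against chance. In the simulated data 5.8% of 2-fold changes in the more abundant unigenes were called. Most changes of that size in such unigenes would thus be missed with 3 libraries per group.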

Other observations

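The average of the 3 MeJA times against untreated stem, the correlations below and the tests of the 3 patterns were chosen only after results were seen, except the tests of a few unigenes taking a large share of the FPKM and of elapsed time. Averaged over the 3 times, 5 of 37796 unigenes passed limma (1 higher and 4 lower, 2640 at an unadjusted p below 0.05, where chance alone gives 1890). They include R2R3-MYB 58, of a family of transcription factors that regulates phenylpropanoid and other secondary metabolism, with 9.32 ± 5.01 FPKM in untreated stem (mean ± SD, n = 3) and at most 0.88 in the 9 treated libraries (limma adjusted p = 0.0153). DN55815_c0_g2, chosen after its values were seen, with a predicted protein of 314 amino acids and no family motif, had 62.1 ± 10.1 FPKM in untreated stem and 21.5 ± 2.88 in the 9 treated libraries, all of which lay below all untreated ones (limma adjusted p = 0.0403). DN103525_c0_g1, chosen in the same way, had 2.23, 3.27 and 2.84 FPKM in untreated stem and was listed at 0 in all treated libraries (limma adjusted p = 0.0107). The others, DN98062_c0_g1 and DN64360_c1_g1, also passed at single times (adjusted p = 0.00558 and 0.0107 here). Without untreated replicate 2 the count was 0, and without untreated replicate 3 it was 22. It was 2 with a pseudocount of 0.1 FPKM, 3 with the lignin covariate and 22 with array quality weights. It was 1 with a filter of 5 FPKM or the filter counted without untreated replicate 3, neither of which left any of the 4 falls. The filter of 5 FPKM did not test DN98062_c0_g1 and DN103525_c0_g1. The other filter did not test these or R2R3-MYB 58, so their loss was fixed in advance.

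The list means were also compared by exact permutation over the 220 ways to choose 3 of 12 libraries, 2-sided and adjusted over 28 lists. The plastid MEP list was 1.29 lower after MeJA on the log2 scale by its mean (difference -1.29, exact permutation p = 0.0136, adjusted 0.255), with 7 of 9 treated libraries below all untreated ones. Prenyl diphosphate synthases gave -0.601 (exact permutation p = 0.0227, adjusted 0.255), triterpene and sterol synthesis 0.515 (0.0273, adjusted 0.255), cell wall 0.587 (0.0455, adjusted 0.305) and jasmonate signalling -0.462 (0.0545, adjusted 0.305). The other lists that camera called at single times had larger p. Flavonoid gave -1.24 (exact permutation p = 0.105, adjusted 0.477), ABCG transporters -0.315 (0.123, adjusted 0.477) and heat shock and dehydration 0.446 (0.136, adjusted 0.477). NBS resistance genes gave 0.189 (0.518, adjusted 0.91), R2R3-MYB factors -0.0803 (0.568, adjusted 0.91) and housekeeping 0.027 (0.845, adjusted 0.91). None passed the adjustment. The smallest p that these splits can give is 0.0045, so a list that stood alone at this p could not pass when adjusted over 28 lists.

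The first pattern is the set of 18883 unigenes found in untreated replicate 3 alone, of which 66.4% had a predicted coding sequence against 36% to 56.8% of the sets of other libraries. Deeper sequencing is argued against by its estimated relative depth of 0.92, since libraries at 0.973 to 1.52 held at most 4001 such unigenes. Reads from another organism stay open, since housekeeping and cell division motifs made up 0.169% of this set (0.0994% in the other 11 together) and up to 0.246% of the set of another library, and the fungal Zn2Cys6 motif 0.0212% (0.00621%) and up to 0.0345%. RNA of photosynthetic organisms on the stem stays open too, since light-harvesting unigenes made up 0.0794% (15 unigenes; 0.00311% in the other 11 together) against at most 0.0291% (1 unigene) elsewhere, less than the 3 times set as the bound. Genes of the tree itself that only this sample expressed were not tested and stay open.

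The second pattern is the spread of wood-forming transcripts along the first component. A few abundant unigenes taking a large share of the FPKM are argued against, since the range of the lignin list mean was 2.32 as deposited and 2.55 after centring. Different depth as the main cause is argued against by a correlation of -0.294 between the component and estimated relative depth (permutation p = 0.35). With 12 libraries this value cannot exclude that depth plays a part. A varying share of wood-forming tissue in the samples may account for it, since the lignin list followed the cellulose synthases (r = 0.968) and the tubulins (r = 0.96, permutation p = 1e-05, adjusted p = 2e-05, rho = 0.902, 0.924 without the 2 libraries farthest out, 0.959 within groups). Regulation of these genes within the same tissue would give the same values, was not tested and stays open.

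The third pattern is the lower plastid MEP list after MeJA. Without untreated replicate 2 the camera call with the preset correlation held (highest adjusted p over the 3 times 0.00189), although the list difference shrank to -0.485 at 30 days. Untreated replicate 3 had a list mean of 3.985, below MeJA 30 days replicates 1 and 2 (4.072 and 4.018). The camera call also held with the lignin covariate (highest adjusted p 9.76e-05) and over 3 scalings (0.000307). The preset correlation of 0.01 lies below the 0.385 estimated between members, so these tests leave untreated replicate 2 and wood-forming tissue open as causes. Scaling as the whole cause is argued against by size. Centring shifted the libraries by -0.269 to 0.163 on the log2 scale, against differences in list mean of -1.43, -1.43 and -0.992. Elapsed time and MeJA cannot be told apart, as 0 untreated libraries carry a day in the labels. The lower list after MeJA stays a hypothesis, since it did not pass with an estimated correlation (adjusted p = 0.586, 0.316 and 0.585).

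Over the 12 libraries the plastid MEP list mean and that of the class I terpene synthases had r = 0.452 (permutation p = 0.14, adjusted p = 0.14, rho = 0.497, permutation p = 0.1, adjusted p = 0.1, 0.177 without untreated replicates 1 and 2, 0.685 within groups), which leaves open whether they vary together. The plastid MEP and jasmonate signalling list means had r = 0.652 (permutation p = 0.01, adjusted p = 0.014, rho = 0.811, permutation p = 0.0022, adjusted p = 0.0029). Without untreated replicates 1 and 2 it was 0.499 (permutation p = 0.14) and within groups 0.399, which leaves open whether they vary together.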
